A study of Homo sapiens with 16 samples.

How the data were processed

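RNA from 8 groups of cells, the cisplatin-resistant and sensitive variants of A2780, OVCAR3, H23 and H460 with 2 replicates each, was hybridised to one-colour long noncoding RNA arrays. Per the labels' protocols, total RNA was extracted with TRIzol and treated with DNase, ribosomal RNA was removed, and the labelling used random primers along the whole transcript. The labels describe the replicates as independent. The deposited scanner files hold spot intensity values that the authors obtained with Agilent Feature Extraction 11.0.1.1, per the file headers. Their processed intensity is background-subtracted and not normalized between arrays, per the file headers. The files also hold flags for spots well above background, for outliers and for saturation. The deposited series table holds the authors' processed log2 values of 51295 probes, each well above background on at least 1 array. Its steps are not given in the sources used here. Each column correlated at 0.999 or more (after rounding) with the quantile-normalized log2 intensity of its own array, so its scale is log2 and its direction that of the signal, and its column medians lay between 6.93 and 6.94.

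Spots of 1 probe were averaged after outlier-flagged spots had been left out. The 1439 array control spots and the 600 spots of negative control probes were left out as well. The log2 processed signal minus the 75th percentile of its array was the main measure, and a scaled log2 value of 0 is thus the 75th percentile. Those percentiles lay between 373 and 599 intensity units. A model with 8 group means was fitted to all 16 arrays with limma 3.58.1 (lmFit and eBayes with a trend) in R 4.3.3, which left 8 residual degrees of freedom. In each line, probes well above background on both arrays of at least 1 of its 2 groups were tested, resistant minus sensitive. A probe was called at a Benjamini-Hochberg adjusted p under 0.05 and at least 2-fold. Adjusted p values in the text are limma's unless another test is named. The average change over lines was tested with limma on the 4 line differences, with no fold threshold, over probes tested in all 4 lines. The difference between lung and ovarian lines was tested as a contrast of the 4 line differences. Overlaps were compared with independent lists and with 1000 permutations of the probes within each line. Directions were permuted within each line 1000 times for 3 or more lines and 10000 times for pairs.

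The files name most probes by the maker's IDs alone. The 20 probes with a RefSeq accession were named through a RefSeq gene table of assembly GRCh38.p14, and 2 of these genes are not reported here. The file headers give hg19, so no coordinates are printed. The 30 gene lists fixed beforehand (DNA repair, drug transport and others), the p53 target and cancer-testis comparisons, the pairs of antisense transcripts with their genes, the split into noncoding RNAs and mRNAs and the rule for choosing named genes all need gene names and were not run. Printed probe IDs were limited to 2 that were higher and 2 that were lower. They were taken from the probes called in the same direction in the most lines, well above background on all 16 arrays, with the largest mean difference, a rule chosen after the data were examined.

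The alternatives were quantile normalization, normexp background correction (offset 50) with quantile normalization, the authors' log2 values, no filter or a strict filter on dim probes, a replicate block, the scan batch as a block, no fold threshold, a fit of each line alone, other units of replication, and leaving out each array. The mean spot signal is not among the columns of the files, so normexp used the median spot signal. All were chosen before the data were examined, except a crossed replicate block and the correlations without the array scanned apart. The arrays fell into 3 scan batches: the ovarian lines except resistant replicate 2 of A2780, that array alone, and the lung lines. On a slide, the sensitive arrays of a line lay in positions 1 and 2 and the resistant ones in positions 3 and 4, with the exception of the array scanned apart. On all 16 arrays the 3 other arrays of the same line correlated better than any array of another line.

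The fit was tested on simulated data with the group means and spread of 39903 probes, 200 of them changed in each line. Of changes of 1.5 on the log2 scale, between 61.2% and 67.2% were recovered per line, of changes of 2 between 74.6% and 85.1%, and of changes of 3 between 90.9% and 95.5%. There were 5 to 13 false calls per line. The simulation draws the spread independently for each array and so leaves out deviations common to many probes of 1 array. It gives a probe the same spread in every line and so leaves out differences in spread between lines. The measured SD of the difference between resistant replicates was 0.69 in A2780, 0.46 in OVCAR3, 0.33 in H23 and 0.67 in H460. Between sensitive replicates it was 0.33, 0.41, 0.32 and 0.46 in the same order. The similar recovery therefore does not show that real changes were equally detectable in each line.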

Results

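Gene expression was measured in 4 established human cancer cell lines and in a cisplatin-resistant variant of each. Cisplatin is a platinum drug that damages DNA. A2780 and OVCAR3 are ovarian cancer lines and H23 and H460 are lung cancer lines. The resistant variants had been raised by exposing the parental, sensitive cells to increasing doses over 6 to 18 months. Each of the 8 groups had 2 biological replicates, described in the labels as independent, so 16 one-colour arrays were compared. The array carries probes for long noncoding RNAs and for mRNAs, and the series title asks which noncoding transcripts differ in resistant cells. Between 65.6% and 78.7% of the probes were well above background on an array, and no spot of these probes was saturated. The number of arrays, 2 per group, limits the precision of every value below.

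The files do not pair 58945 of the 58965 probes with genes. The other 20 probes carry RefSeq transcript accessions, and all 20 matched a gene symbol, so gene names are limited to these. They are mostly genes active in all cells, among them actins (ACTB, ACTG1), ribosomal proteins (RPLP1, RPL10, RPS18), glycolytic enzymes (GAPDH, PGK1) and the histone gene H3-3A. The RPL10 probe read low, at -2.14 in sensitive A2780 cells against 9.43 for RPLP1. Of the 20 genes, 18 are described here.

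PGK1, which encodes the glycolytic enzyme phosphoglycerate kinase 1, was the one gene of these 18 past the adjusted p threshold in any line. In A2780 its signal was 2.68 ± 0.22 (SD, n = 2) in resistant cells and 3.48 ± 0.11 (SD, n = 2) in sensitive ones. The difference was -0.79 (SE 0.20), with an adjusted p of 0.0248 by limma, and was smaller than 2-fold. A pair of control probes against the 3' and 5' ends of PGK1 gave differences of -0.65 (SE 0.23) and -0.90 (SE 0.26) in A2780, with both resistant arrays below both sensitive arrays. Taken on their own, those control probes did not pass a threshold of 0.05 (limma adjusted p over the control probes 0.395 and 0.274). The PGK1 probe gave 0.45 in H23, 0.28 in H460 and -0.32 in OVCAR3 (SE 0.20 each), none of which passed the test. The PGK1 change was higher in the lung lines than in the ovarian lines by 0.92 (SE 0.20; limma adjusted p 0.0165), again below 2-fold. With the 4 lines as replicates its adjusted p was 0.878 (unadjusted 0.0364), and the limma F-test among the 4 lines gave an adjusted p of 0.0318 over all probes and 0.0724 over the 20 named probes. Without resistant replicate 1, sensitive replicate 1 or sensitive replicate 2 of A2780, the adjusted p of PGK1 in that line was 0.0791, 0.171 and 0.0888, and with the line's own 4 arrays 0.104, in a range of 0.0103 to 0.171.

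**Figure D1:**
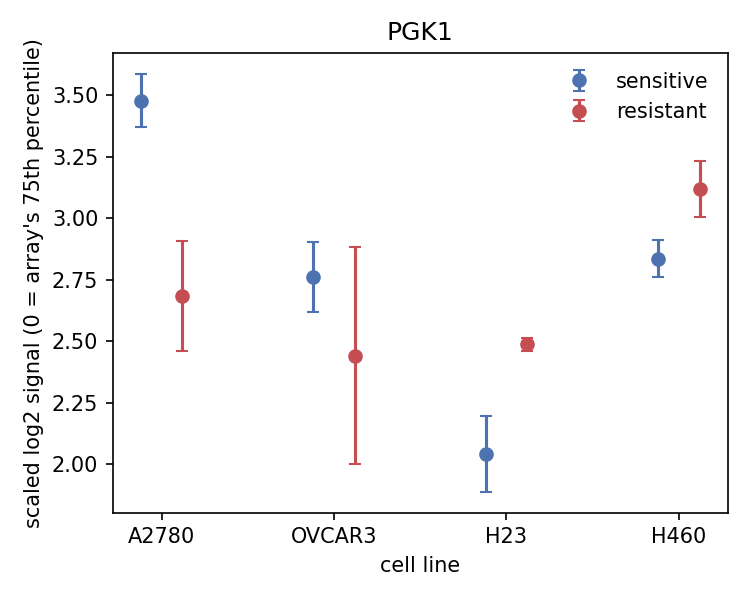
Scaled log2 signal of PGK1 (vertical axis, 0 is each array's 75th percentile) in sensitive and resistant cells of the 4 lines (horizontal axis); points are means and bars are SDs of 2 arrays. In A2780 the signal was 2.68 in resistant and 3.48 in sensitive cells, a difference of -0.79.

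The other genes of the 18 did not pass the test in any line. GAPDH differed by -0.14 in A2780, -0.12 in OVCAR3, -0.02 in H23 and -0.16 in H460 (SE 0.27 each). ACTB differed by -0.05, -0.18, -0.01 and -0.11 in the same order (SE 0.28 each). In OVCAR3 and H460 all 18 differed by less than 0.5 in size, and in A2780 and H23 16 of the 18 did. Besides PGK1, the largest differences were those of GRM4, a glutamate receptor gene, in A2780 (-0.75, SE 0.23, adjusted p 0.0575 by limma), of ARHGDIA in H23 (0.66, SE 0.23, adjusted p 0.12 by limma) and of MTX1 in H23 (-0.58, SE 0.21, adjusted p 0.132 by limma). The GRM4 probe was dim in A2780, at -3.28 in resistant and -2.53 in sensitive cells. Some negative control probes read higher there, such as Negative059 at -2.34 and -2.04.

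With the spread between replicates pooled over all 16 arrays, A2780 had the most changed probes. With each line's own 4 arrays H23 had the most, 2773 against 2104 in A2780. In A2780, 3269 of 43987 tested probes were called, with 1834 higher and 1435 lower in resistant cells. Among the called probes well above background on all 4 arrays of the line, the median difference was 2.64-fold for the 1549 higher ones and 2.80-fold for the 790 lower ones, and 524 differed at least 4-fold. Another 207 called probes were well above background on both resistant arrays and on neither sensitive array, and 418 showed the opposite. Resistant replicate 1 of A2780 correlated at 0.975 and 0.976 with the sensitive arrays and at 0.973 with resistant replicate 2. The latter correlated at 0.953 and 0.954 with the sensitive arrays, and these with each other at 0.993. Resistant replicate 2 of A2780 was scanned apart, with 65.6% of its probes well above background against 74.3% for resistant replicate 1. Its negative control signal was 51.0 intensity units, against 19.7 to 28.8 on the other arrays. It is alone in its scan batch, so a batch block amounts to leaving it out and does not correct for scanning. With the scan batch as a block 2570 probes were called. Without resistant replicate 1 the count was 6915, with 34.4% of the calls higher in resistant cells in place of 56.1%.

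In OVCAR3, 1711 of 45518 tested probes were called, 813 higher and 898 lower in resistant cells. The median difference of those measured on all 4 arrays was 2.81-fold for higher and 2.79-fold for lower probes, and 336 differed at least 4-fold. In addition, 94 were above background on the resistant arrays alone and 197 on the sensitive arrays alone. The count was 1117 without resistant replicate 1 and 1013 without sensitive replicate 2, and the share of higher calls lay between 41.6% and 54.2% without 1 OVCAR3 array.

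In H23, 2168 of 45108 tested probes were called, and 1373 of these were lower in resistant cells against 795 higher ones. The median difference of those measured on all 4 arrays was 2.47-fold for higher and 2.59-fold for lower probes, and 275 differed at least 4-fold. Another 65 were above background on the resistant arrays alone and 220 on the sensitive arrays alone. The count was 1240 without resistant replicate 1 and 1211 without sensitive replicate 1.

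In H460, 91 of 42921 tested probes were called, 49 higher and 42 lower in resistant cells. The resistant H460 arrays correlated with each other at r = 0.973 across probes, while resistant replicate 2 correlated with the sensitive arrays at 0.988 and 0.985 and these with each other at 0.987. Resistant replicate 1 correlated with the sensitive arrays at 0.972 and 0.978, so it was the H460 array least like the others. The named genes H3-3A, PRMT1 and EIF3D had SDs of 0.90, 0.88 and 0.80 (n = 2) between the resistant H460 arrays, against at most 0.28 in each other group. Without resistant replicate 2 of H460 the count was 1212, with 40.0% higher in resistant cells in place of 53.8%. It was 55 without sensitive replicate 1, with 30.9% higher, and 75 without sensitive replicate 2, with 37.3% higher. Leaving out 1 array of another line changed the H460 count as well. With the line's own 4 arrays alone it was 0 by limma. An unadjusted p under 0.05 was then found for 1725 probes, below the share of 0.05 that chance gives.

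**Figure D2:**
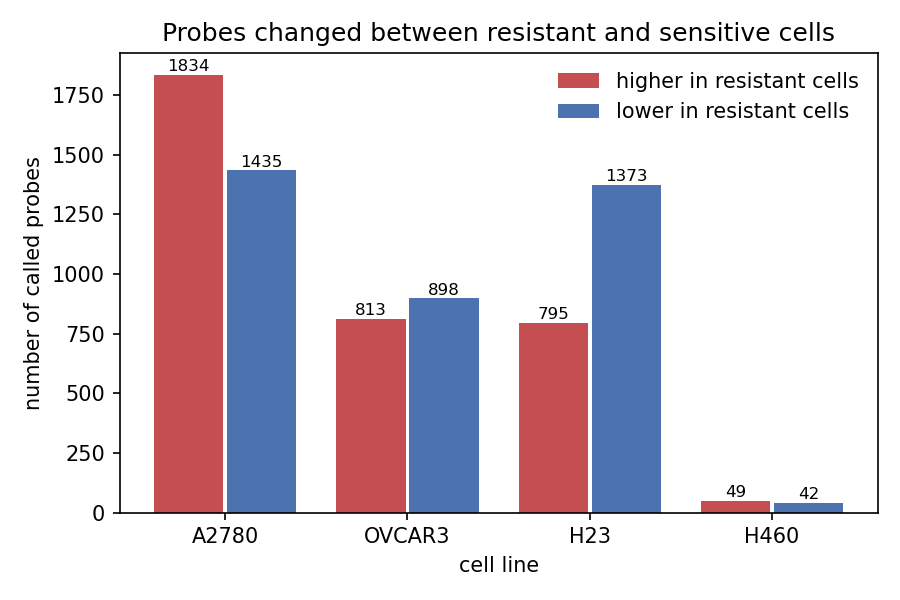
Number of called probes (vertical axis) in each cell line (horizontal axis), split by direction; each bar is a count over 4 arrays of the line, with the count written above it. A2780 had 1834 higher and 1435 lower probes and H460 had 49 and 42.

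To ask whether resistance altered the same transcripts in different lines, the calls were compared across lines. A total of 26 probes were called in the same direction in 3 or more lines. Of these, 7 were higher in 3 lines, 17 were lower in 3 lines and 2 were lower in 4 lines. The count of 26 became 11 with normexp and quantile normalization, 13 with the strict filter on dim probes and 46 with no fold threshold. Independent lists of these sizes would share 0.82 such probes, and 1000 permutations of the probes within each line gave at most 7 (one-sided permutation p = 0.001, the smallest they can give). The lines share 1 estimate of the spread of a probe, so a probe with a low spread is more easily called in several lines. Both comparisons leave this out, and its part in the excess was not tested. The directions were not shared beyond chance: 108 probes were called in 3 or more lines in any direction, and permuting the directions within each line gave a median of 27 probes with 3 or more calls in the same direction (95% range 19 to 37, one-sided permutation p = 0.645). Of the 6235 probes called in at least 1 line, 5341 were called in exactly 1.

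The pairs of lines showed the same pattern. A2780 and OVCAR3 shared 167 probes called in the same direction and 188 called in opposite directions, where independent lists would give 43.8 and 43.9. A2780 and H23 shared 190 and 231, against 56.2 and 61.5. OVCAR3 and H23 shared 151 and 128, against 30.6 and 30.4. These expected counts leave out the shared spread as well. In none of the 6 pairs did the number in the same direction differ from permuted directions after adjustment (permutation test, two-sided, adjusted p from 0.239 to 0.71). The smallest unadjusted p, 0.0399, was that of OVCAR3 and H460, which shared 12 probes in the same direction and 3 in opposite directions.

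**Figure D3:**
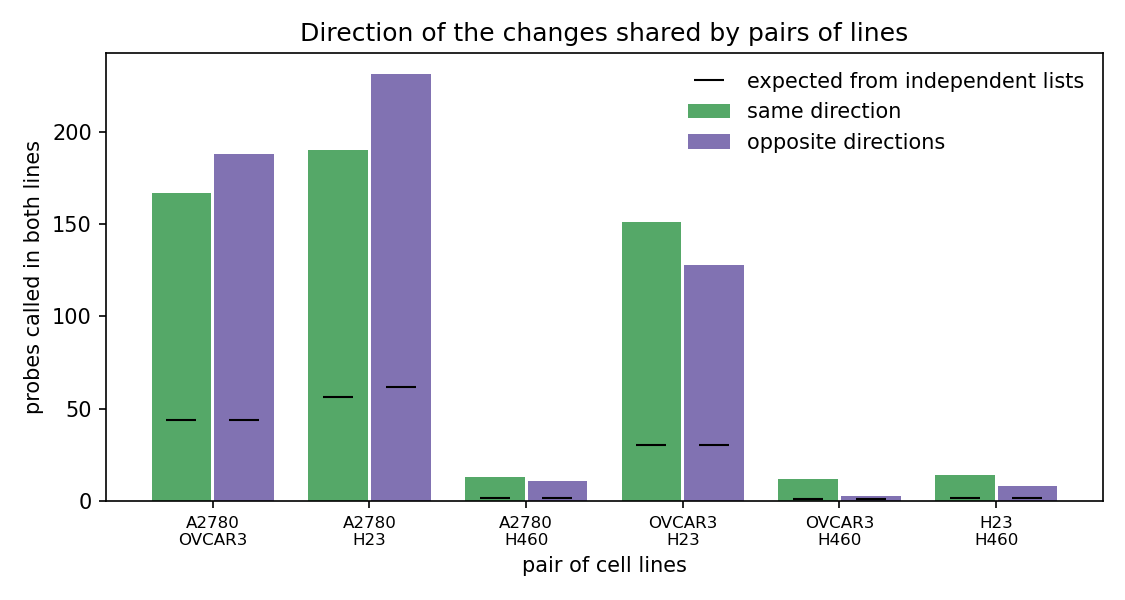
Number of probes called in both lines of a pair (vertical axis) for the 6 pairs of lines (horizontal axis), by whether the changes had the same or opposite directions; horizontal marks are the counts expected from independent lists. A2780 and H23 shared 190 probes in the same direction and 231 in opposite directions.

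Among the 26 probes, 6 of the higher and 7 of the lower ones were well above background on all 16 arrays. Probe ASHGA5P046986 was 18.0-fold higher in resistant A2780 cells (log2 difference 4.17, SE 0.26), 3.51-fold higher in OVCAR3 and 4.35-fold higher in H460. In H23 the difference of 0.85 was not called (limma adjusted p 0.0695). The scaled log2 level of this probe in sensitive cells was low in A2780 (-4.52) and H460 (-4.17), so the size of these folds is uncertain. In sensitive A2780 cells most negative control probes read lower. Some read higher, among them Negative008 (-4.42), Negative051 (-3.47) and Negative010 (-0.12). Probe ASHGA5P034532 was 8.61-fold higher in resistant H23 cells (log2 difference 3.11, SE 0.19), 2.25-fold higher in A2780 and 3.08-fold higher in OVCAR3, while in H460 the difference of 0.94 was not called (limma adjusted p 0.0884). Probe ASHGA5P045708 was lower in resistant cells of all 4 lines, with log2 differences of -1.82 in A2780, -2.04 in OVCAR3, -1.59 in H23 and -1.27 in H460 (SE 0.22 each; limma adjusted p from 0.000129 to 0.0397). Probe ASHGA5P055073 differed by -4.87 in A2780, -1.23 in OVCAR3 and -1.90 in H23 (SE 0.25 each) and by -0.04 in H460. Its level in H460 was low in both resistant (-3.39) and sensitive cells (-3.35). Levels were low as well, among others, for ASHGA5P055073 in resistant A2780 (-2.72) and H23 cells (-3.81) and for ASHGA5P034532 in sensitive OVCAR3 cells (-3.51). The size of those changes is therefore also uncertain.

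Taking the cell line as the replicate, no probe of 39903 passed an adjusted p of 0.05 for an average change over the 4 lines by limma. An unadjusted p under 0.05 was found for 553, below the share of 0.05 that chance gives. With the spread between arrays in place of that between lines, 2412 probes passed, 1204 of them higher in resistant cells. Across 39923 probes, which are not independent replicates, the resistant minus sensitive differences of H23 and H460 correlated with a Spearman coefficient of 0.25. The differences of A2780 correlated at -0.12 with OVCAR3, -0.07 with H23 and -0.08 with H460, and OVCAR3 correlated at 0.06 with H23 and 0.07 with H460. For comparison, differences between the 2 replicates of a group correlated between lines at -0.41 to 0.31 over 24 pairs, with a median size of 0.087. No value lay outside that range, while 0.25 and -0.12 exceeded that median in size. The replicate differences are of single arrays and have an arbitrary sign, so their range is a rough guide.

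The change differed between the lung and the ovarian lines for 2391 of 48941 tested probes, with 974 higher in the lung lines and 1417 higher in the ovarian lines. In 1777 of these both lines of 1 tissue lay on the same side of both lines of the other, and in 1022 the lung lines changed one way and the ovarian lines the other. The probes were chosen by this contrast, which favours both counts. Of the 2391 probes, 46.8% were also called in A2780. Without resistant replicate 1 of A2780 the count was 3989 and the balance of directions turned, with 2216 higher in the lung lines (55.6%, against 40.7% with all arrays). With the 4 lines as replicates, 2 per tissue, no probe was called by limma. An unadjusted p under 0.05 was then found for 2451, near the share of 0.05 that chance gives. The count of 2391 thus describes these lines and not the tissues. The lung and ovarian arrays were scanned in different batches, and each resistant minus sensitive difference was formed within a batch except that of A2780.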

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

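The tests of permuted directions, of whole lines with exchanged labels, and of a wrong label in H460 were chosen after the results had been seen, as were the limit of the comparison to splits that keep the groups of all 4 lines and the test of a step between array positions. The bootstrap ranges below resample probes, which are not independent, and leave out the spread between arrays and cultures.

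The change between resistant and sensitive cells differed between lung and ovarian lines for 2391 probes and among the 4 lines for 6809 probes (limma F-test, adjusted p under 0.05). When the arrays of each line were split in other ways into 2 and 2, 1 of 100 splits, the real one, gave as many probes for the lung against ovarian contrast, and the highest other split gave 2195. Of the 100, 2 kept the real groups of all 4 lines; the rest mix resistant and sensitive arrays, which puts the changes into the spread, so the comparable splits are too few for a share under 0.05. Exchanging the labels of whole lines gave 1755 to 2868 probes, with 1 of 7 exchanges above the real count. Among these, the exchange that sets A2780 and H23 against OVCAR3 and H460 gave 1977. The one that sets A2780 and H460 against OVCAR3 and H23 gave 2034. PGK1 differed between lung and ovarian lines by 0.92 on the log2 scale, with an adjusted p of 0.0165 by limma with the spread between arrays and 0.878 with the 4 lines as replicates.

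With the spread pooled over all arrays A2780 had the most called probes, 3269, while with each line's own 4 arrays H23 had 2773 and A2780 2104, and 1 resistant A2780 array was scanned apart with a higher background. That array alone as the source of the calls is argued against by the 2549 probes called without it with the pooled spread, above 0.5 of the full count, of which 2163 were among the 3269. A larger change in A2780 cells is consistent with the SD of the change that both replicates share, estimated from differences with no array in common: 0.54 in A2780 (0.54 also with the arrays paired the other way), against 0.33 and 0.37 in OVCAR3 and 0.45 and 0.46 in H23. Why resistant A2780 cells would differ more was not tested.

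H460 had 91 called probes, and 1 array decided that count: 1212 probes were called without resistant replicate 2 and 77 without resistant replicate 1. The SD of the shared change in H460 was 0 with same-numbered arrays, where the differences correlated at -0.22, which independent noise cannot give, and 0.10 (bootstrap range 0.08 to 0.12) with the arrays paired the other way, where they correlated at 0.04. The latter is 0.273 of the lowest SD of the other lines in that pairing. The deviations of the same arrays were not independent in the first pairing and may not be in the second. The SD therefore does not decide between noisier arrays that hide a shared change and a smaller shared change. Over the 1212 probes, replicate 2 carried 0.129 of the change of replicate 1 (bootstrap range 0.104 to 0.154), but these probes were called without replicate 2, which favours large differences in replicate 1, so the ratio decides nothing and a wrong label stays open. Deviations of replicate 1 alone were not separated from these.

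The 26 probes called in the same direction in 3 or more lines exceeded permuted probes, which leave out the spread that the lines share. In 2 of 100 splits of the arrays as many were found, the highest other split also giving 26. Those 2 kept the real groups of all 4 lines, too few for a share under 0.05. The step of 1 array position was 0.00203 of the change (bootstrap range -0.0189 to 0.0262), against 0.5 for an even gradient. That step is the difference between replicates, and calls require small differences between replicates. The choice of these probes thus favours a low ratio, so the ratio decides nothing and a gradient stays open. Resistant replicate 2 of A2780 lay in position 1 and yet carried 0.87 of the change of replicate 1 (bootstrap range 0.657 to 1.27) over 29 shared probes chosen without it, which argues against a step between positions in A2780 and leaves one open in the other lines. With directions permuted within lines the median was 27, and exchanging the labels of whole lines gave 24 to 35, with at least as many in 6 of 7 exchanges, so these probes may be ones that change readily, with no direction in common.

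For the average over the 4 lines, 8 exchanges of whole lines are too few for a share under 0.05 (all 8 gave 0 probes, so the real value and the highest other are both 0). With the spread between arrays, 2 of 100 splits gave as many as the real 2412 probes, and the highest other gave 2806, a split with the real groups and the labels of H23 and H460 exchanged, and the comparable splits are again too few for a share under 0.05. Of the 7 other exchanges of whole lines, 3 gave at least as many probes, up to 3489.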

How the results depend on the processing

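The crossed replicate block and the correlations without the array scanned apart were chosen after the data were examined, all other alternatives before. Quantile normalization, the authors' values and no filter on dim probes kept every count of probes within 1.5 times. Causes of changed counts were not tested, except where fewer probes or arrays were used.

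In A2780 (3269), OVCAR3 (1711) and H23 (2168), normexp with quantile normalization gave 1682, 1052 and 1139 called probes. The strict filter, which tests fewer probes, gave 1863, 847 and 1348, and 37 in H460 (91). The probes in the same direction in 3 or more lines (26) numbered 11 with normexp and 13 with the strict filter, and those differing between lung and ovarian lines (2391) numbered 1183 and 1263. With no fold threshold the counts were 5036 in A2780, 3759 in H23, 46 in 3 or more lines and 3727 between tissues. With a line's own 4 arrays, which leave 2 residual degrees of freedom, they were 2104 in A2780, 1595 in OVCAR3, 2773 in H23 and 0 in H460 (1725 at an unadjusted p under 0.05 by limma). The share of higher calls in H460 was 53.8%, and 38.5% with normexp. The 4 lines as replicates gave 0 probes between tissues, and the mean of the 4 contrasts gave 2412 on average over lines, against 0.

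With the replicate block the counts were 2911, 1307 and 1731 in A2780, OVCAR3 and H23, 14 in H460, 19 in 3 or more lines and 1686 between tissues. The block leaves the 4 line differences as they are, so the average over lines stays at 0. Same-numbered deviations correlated at 0.02, -0.18, -0.01 and -0.26 in A2780, OVCAR3, H23 and H460, so the numbers do not pair the arrays. With crossed numbers, the block gave 1367 calls in OVCAR3 and 24 in H460. The array scanned apart is alone in its batch, so a block for the scan batch amounts to leaving that array out. The scan batch as a block gave 2570 in A2780 and 147 in H460.

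Leaving out each of the 16 arrays gave 2372 to 6915 called probes in A2780, 1013 to 1863 in OVCAR3, 1211 to 2296 in H23 and 49 to 1212 in H460. A lone array is then assumed to vary like the other groups. It gave 18 to 50 probes in 3 or more lines, where 50 came without H460 resistant replicate 2, 1874 to 3989 between tissues, and 0 on average over lines. PGK1 in A2780 was past an adjusted p of 0.05 in 19 of 24 alternatives (differences -0.95 to -0.64), with the sign kept in all. It was 0.0915 with the replicate block, 0.104 with the line's own 4 arrays, and above 0.05 without any of 3 A2780 arrays (0.0791 to 0.171). Leaving out an array of another line kept the PGK1 difference in A2780 at -0.79, so those alternatives varied only its spread. Without the array scanned apart, A2780 differences correlated at -0.07, -0.09 and -0.07 with OVCAR3, H23 and H460. Gene lists and antisense pairs were not run. Probes below background, 21.3% to 34.4% of an array, limit what could be called.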

Other observations

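The called probes were ones whose level also differed between unrelated sensitive lines. Among probes tested in A2780, the SD of the level between the sensitive cells of the other 3 lines had a median of 0.84 on the log2 scale for called probes and 0.39 for the rest. The medians were 0.96 and 0.38 for OVCAR3, 1.00 and 0.39 for H23, and 1.45 and 0.40 for H460. Within deciles of level, the ratio was 2.16 in A2780, the lowest of the 4 lines, and 3.60 in H460, the highest (permutation test within deciles, one-sided p = 0.001 in each line, the smallest 1000 permutations can give; probes are not independent). A candidate explanation is that the transcripts altered in resistant cells are those that cell lines can switch in any case; how this relates to cisplatin was not tested.

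The 3' minus 5' difference of the GAPDH control probes was 0.38 ± 0.03 (SD, n = 2) on the log2 scale in resistant H23 cells and 0.72 ± 0.02 in sensitive ones. In the other lines the resistant minus sensitive difference of that value was -0.12 in A2780, -0.30 in OVCAR3 and -0.29 in H460. For PGK1 it was 0.25 in A2780, 0.11 in OVCAR3, -0.17 in H23 and -0.20 in H460.

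Of 53 array control probes not named for a human, mouse or rat gene, 1, ERCC-00062_278, was above background on all spots of all 16 arrays at a level above the 75th percentile. Its scaled log2 signal ranged from 2.61 to 5.55, and replicates differed by an SD of up to 1.45. It did not differ between resistant and sensitive cells by limma in any line.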
